A study of Homo sapiens with 12 samples.

How the data were processed

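RNA of 293T cells, a human embryonic kidney line that carries the SV40 large T antigen, was measured on 12 arrays in 4 groups of 3: cells with a non-target control hairpin and cells with 1 of 3 short hairpin RNAs (shRNA1, shRNA2, shRNA3) against RBFOX2. Per the labels' protocols, hairpins were delivered by lentivirus, puromycin at 1 ug/mL was begun 48 hours after infection and kept for 10 days, and total RNA was then extracted with Trizol. The array carries probe sets for single exons and for exon-exon junctions. Per the submitters' processing notes, the deposited values were made with Affymetrix Expression Console and RMA. Their versions, the settings and the genome build are not given in the sources used here. The values the authors deposited are on a log2 scale, as the range of the values shows, and were used as they are.

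The table held 914585 rows, of which 573909 were exon probe sets, 339146 junction probe sets and 1530 controls, which were left out. In the platform annotation 672085 probe sets had 1 gene symbol, 39483 had several and 201487 had none. Only probe sets with 1 symbol were used for genes. Of 22085 symbols on the array, 19540 were current, 2474 were updated through a table of RefSeq gene names (assembly GRCh38.p14, used for names only) and 71 had no match and kept the array's symbol. Identical copies of a probe set within a gene, 26130 in all, were counted once. That choice was made after a first look at the values, and the result with the copies kept is among the alternatives. No genome sequence and no probe set coordinates were used here, so a planned search for the RBFOX binding motif near changed exons was not run.

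Array medians lay between 7.24 and 7.27 on the log2 scale, and correlations between arrays, taken across probe sets, lay between 0.991 and 0.995. No 2 arrays held identical values. A probe set was kept if its mean over the 12 arrays was above the 40th percentile of all probe sets, log2 6.53, which left 547833. A gene's value was the mean log2 value of its kept probe sets, with at least 3, giving 16648 genes. The splicing index of a probe set was its log2 value minus the mean of the other kept probe sets of its gene on the same array, for genes with at least 4, giving 417377 probe sets in 15891 genes. It measures unequal change within a gene. Single kept probe sets were also tested, 516081 in all, including those without a gene name.

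All tests used limma (version 3.58.1, lmFit and eBayes, two-sided) in R 4.3.3, with the data.table package (version 1.17.8). The 4 groups were fitted together without a block, which gave 8 residual degrees of freedom. Same-numbered control and shRNA2 arrays, but not all of those of any other pair of groups, deviated together over genes (r of 0.202, 0.432 and 0.264), so counts for shRNA2 that moved by more than 1.5 times with the replicate number as a block are given with that value. Contrasts were each shRNA minus control, the mean of the 3 shRNAs minus control, and the 3 differences between shRNAs. Adjusted p-values are Benjamini-Hochberg values over all features of a contrast. A gene or single probe set was called at an adjusted p below 0.05, and a splicing index at an adjusted p below 0.05 with at least a 1.5-fold difference. A feature changed by all 3 shRNAs had to be called in each contrast with the same sign. Errors printed with changes are standard errors (SE) of the fit, with 3 arrays in each group. The labels give replicate numbers but nothing says that replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

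Named genes followed a rule. It took the 3 RBFOX genes, the 10 highest and 10 lowest genes among those changed by all 3 shRNAs, ranked by the smallest of the 3 changes, the 5 largest rises and falls per shRNA, the 3 largest each way between shRNAs, and up to 4 members per gene list by the mean change. For splicing, the 10 highest and 10 lowest probe sets called in all 3 contrasts were named, at most 1 per gene. Genes named outside this rule were chosen after their values were seen, and this is said where they appear. Of the gene lists that were fixed, 30 had enough measured members to be tested and 3 did not. The 30 were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, and adjusted over 120 tests (30 lists in 4 contrasts). Known RBFOX targets were set against 10000 random gene lists matched on the number of kept probe sets. The groups, tests, thresholds, gene lists, naming rule and most alternatives were chosen before the data were examined. Because all contrasts use the same 3 control arrays, overlaps were set beside simulated unchanged groups and beside independent lists.

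The steps were tested on simulated data built from the real values, with 200 changed features. Each feature was drawn independently, so false calls from arrays that deviate in many genes together are not covered. For shRNA1 minus control over 16648 genes, 85.1% of genes changed by 0.25 on the log2 scale were recovered, 98.5% of those changed by 0.5 and 100% of those changed by 1, with 10 false calls among 199. For the splicing index over 417377 probe sets, 76.1% were recovered at 0.75, 85.1% at 1 and 100% at 2, with 2 false calls among 176. Alternatives covered the level filter, the median in place of the mean, renewed quantile normalization, centring of arrays, the eBayes prior, array weights, fits of only the groups compared, the replicate number as a block, thresholds of size, and leaving out each array. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.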

Results

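RNA levels were compared between 293T cells carrying a non-target hairpin and cells carrying 1 of 3 hairpins against RBFOX2, an RNA-binding protein that regulates alternative splicing through GCAUG elements in introns. Each of the 4 groups had 3 arrays. The arrays measured exons and exon-exon junctions separately, so that levels of whole genes and the use of single exons and junctions could both be compared. The design asks which transcripts and which exons changed when RBFOX2 was depleted, and whether the hairpins gave the same result.

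RBFOX2 was lower on every knockdown array than on every control array. Its gene value, the mean of 44 probe sets, was 9.59, 9.58 and 9.58 on the control arrays, 8.59, 8.54 and 8.51 with shRNA1, 9.10, 9.11 and 9.16 with shRNA2, and 8.82, 8.84 and 8.85 with shRNA3. This left 48.7% of the control signal with shRNA1, 72.6% with shRNA2 and 59.7% with shRNA3. The log2 changes were -1.04, -0.46 and -0.74 (SE 0.03 each, n = 3 arrays per group; adjusted p = 2.09e-10, 4.79e-06 and 2.14e-08). The median over single probe sets was lower still, at 43.1%, 69.0% and 56.5% of control, and 40 of the 44 probe sets were lower with all 3 hairpins. Called lower were 35, 32 and 34 of them with shRNA1, shRNA2 and shRNA3. Some bright probe sets were not called, such as the exon probe set PSR22012293.hg.1 (level 10.9; changes of -0.24, -0.06 and -0.12). Part of the RBFOX2 signal thus changed little. The hairpins differed from each other in RBFOX2 by 0.58 for shRNA2 minus shRNA1 (adjusted p = 6.94e-07), 0.29 for shRNA3 minus shRNA1 (adjusted p = 0.000182) and -0.28 for shRNA3 minus shRNA2 (adjusted p = 0.000217). The paralogs RBFOX1 (changes of -0.09, -0.03 and 0.02; adjusted p = 0.214, 0.698 and 0.696) and RBFOX3 (0.01, 0.07 and -0.07; adjusted p = 0.939, 0.259 and 0.217) did not pass the test with any hairpin.

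**Figure D1:**
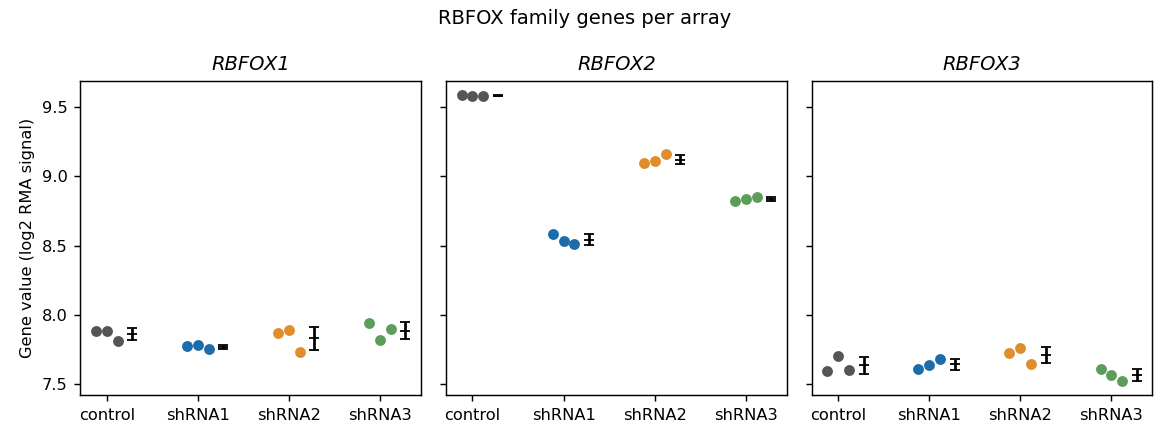
Gene values (log2 RMA signal) of RBFOX1, RBFOX2 and RBFOX3 on each of the 12 arrays, by group, with the group mean and SD beside the points. RBFOX2 lay at about 9.58 on the control arrays and between 8.51 and 9.16 on the knockdown arrays, while RBFOX1 and RBFOX3 differed little between groups next to RBFOX2.

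With all 3 hairpins, 779 of 16648 genes changed in the same direction, 417 higher and 362 lower. The genes whose smallest rise among the 3 hairpins was largest included STC1, a secreted glycoprotein hormone (log2 0.88, 0.86 and 0.88 with shRNA1, shRNA2 and shRNA3; SE 0.16), ZC3H6, a zinc finger gene (0.74, 0.71 and 0.95; SE 0.15), BHLHE40, a transcriptional repressor (0.72, 0.69 and 0.79; SE 0.12), and DDIT4, an inhibitor of mTORC1 signalling (0.74, 0.68 and 0.83; SE 0.12). As a mean over the 3 hairpins STC1 was 1.83-fold and DDIT4 1.68-fold higher. The heparan sulfate endosulfatase SULF1 rose by 0.66, 0.65 and 0.73 (SE 0.11), the collagen receptor kinase DDR2 by 0.79, 0.58 and 0.71 (SE 0.06), the glucose transporter SLC2A3 by 0.77, 0.60 and 0.66 (SE 0.11) and the mitochondrial folate enzyme ALDH1L2 by 0.61, 0.69 and 0.63 (SE 0.07). CLTRN, listed on the array as TMEM27, and the teneurin TENM1, listed as ODZ1, rose 1.71-fold and 1.59-fold on average.

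RBFOX2 aside, falls in all 3 included those of KRTAP19-1, a keratin-associated protein gene (-1.22, -1.11 and -0.78; SE 0.08), and of ID3, an inhibitor of basic helix-loop-helix factors (-0.52, -0.71 and -0.63; SE 0.11). FKBP7, a prolyl isomerase of the endoplasmic reticulum, fell by 0.62, 0.41 and 0.53 (SE 0.06), the histone gene H2BC5 by 0.40, 0.55 and 0.47 (SE 0.04) and the galanin receptor GALR2 by 0.45, 0.49 and 0.40 (SE 0.07). RRH, an opsin homolog, and POLE4, a subunit of DNA polymerase epsilon, were 1.39-fold and 1.33-fold lower on average. ANXA1, which binds phospholipids in the presence of calcium, changed by -0.37, -0.91 and -0.42 (SE 0.08), but was no longer called in all 3 without control replicate 1 (largest adjusted p = 0.0545) or shRNA1 replicate 2 (0.0508). NOSIP changed by -0.37, -0.38 and -0.45 (SE 0.11; adjusted p = 0.0484, 0.0327 and 0.00957). Its call in all 3 was lost without control replicates 1, 2 or 3 (largest adjusted p = 0.171, 0.0588 and 0.103), shRNA1 replicates 1 or 2 (0.170 and 0.197), shRNA2 replicates 2 or 3 (0.142 and 0.0896) or shRNA3 replicates 1, 2 or 3 (0.0561, 0.0575 and 0.0634).

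Changes were small for most of the 779 genes, since 9 changed by at least 1.5-fold with each hairpin and none by at least 2-fold with each hairpin. The count of 779 depended on single arrays. It was 242 without control replicate 1, 316 without control replicate 3, 373 and 283 without shRNA1 replicates 1 and 2, 1233 and 474 without shRNA2 replicates 1 and 2, and 507 without shRNA3 replicate 1. A further 7 genes were called with all 3 hairpins in differing directions. Against the mean of the 3 hairpins 3853 genes changed, 1717 higher and 2136 lower, a count that was 1867 without control replicate 1 and 2144 without control replicate 3.

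**Figure D2:**
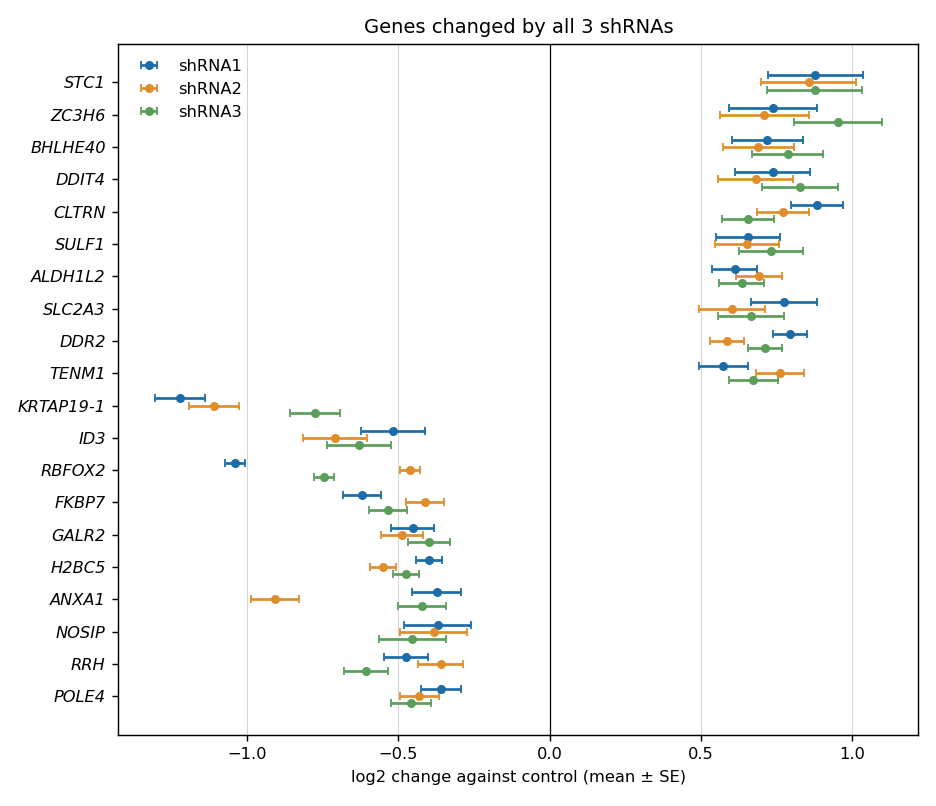
Log2 change against control (horizontal axis; points are fitted means, bars are ± SE) with shRNA1, shRNA2 and shRNA3 for the 10 highest and 10 lowest genes among those changed by all 3 hairpins. STC1 changed by 0.86 to 0.88 with each hairpin, while RBFOX2 fell most with shRNA1 (-1.04) and least with shRNA2 (-0.46).

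Single hairpins changed between 1675 and 4468 genes. With shRNA1, 998 genes rose and 677 fell (1675 in all). SYT11, a synaptotagmin, rose most (0.90 ± 0.06), and CEMIP2, a cell surface hyaluronidase gene listed as TMEM2, fell by 0.79 (SE 0.04; adjusted p = 1.86e-08). With shRNA2, 986 rose and 1436 fell (2422 in all), among them CTH, an enzyme of cysteine synthesis (0.71 ± 0.07), and TAF13, a subunit of TFIID (-0.74 ± 0.05). With shRNA3, 1999 rose and 2469 fell (4468 in all), and the mitotic kinase NEK7 (-0.75 ± 0.06) and HYCC1, listed as FAM126A (-0.65 ± 0.04), were among the largest falls. The gene value of HYCC1 includes 4 probe sets that fell relative to the gene with all 3 hairpins and 1 that rose. A fall of the whole gene is thus not shown for HYCC1. The shRNA1 count was 650, 1113 and 735 without control replicates 1, 2 and 3, and 680 and 493 without shRNA1 replicates 1 and 2. The shRNA2 count was 1107 and 1226 without control replicates 1 and 3 and 1071 without shRNA2 replicate 2, and the shRNA3 count was 2526 and 2848 without those control arrays and 2186 without shRNA3 replicate 1.

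Some genes differed between hairpins directly. NKIRAS2, which encodes an inhibitor of NF-kappaB activation, was lower with shRNA2 than with shRNA1 (-0.58; adjusted p = 3.59e-06), and its changes against control were -0.05, -0.63 and -0.04. C6orf62 was lower with shRNA2 than with shRNA1 (-0.60; adjusted p = 3.93e-06) and than with shRNA3 (0.61 for shRNA3 minus shRNA2; adjusted p = 4.82e-06). NEK7 was lower with shRNA3 than with shRNA1 (-0.70) and shRNA2 (-0.61), and CERS5, a ceramide synthase, likewise (-0.66 and -0.59). CEMIP2 was higher with shRNA2 and shRNA3 than with shRNA1 (0.57 and 0.46), and SYT11 was lower with shRNA2 than with shRNA1 (-0.67; adjusted p = 9.02e-05). The chaperone CLGN differed by -0.71 (SE 0.05; adjusted p = 1.28e-05) and TMEM45A by 0.52 (adjusted p = 2.78e-05) between shRNA3 and shRNA1. SELENOP, a selenium carrier, and LGALS3BP were higher with shRNA3 than with shRNA2 (0.63 ± 0.05 and 0.60 ± 0.04), and the mitochondrial carrier SLC25A24 was lower (-0.49 ± 0.04). GPR50 was higher with shRNA2 than with shRNA1 (0.53), and RWDD4 was higher with shRNA3 than with shRNA1 (0.47).

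In all, 198 genes differed between shRNA2 and shRNA1 (74 higher and 124 lower with shRNA2), 1182 between shRNA3 and shRNA1 (491 higher and 691 lower with shRNA3) and 593 between shRNA3 and shRNA2 (257 higher and 336 lower with shRNA3). The first count was 107, 85 and 83 without shRNA1 replicates 1, 2 and 3. The second was 377, 361 and 367 without those arrays, 2508 without shRNA2 replicate 3, and 291 and 338 without shRNA3 replicates 1 and 3. The last was 377, 1485 and 293 without shRNA2 replicates 1, 2 and 3, and 279 and 245 without shRNA3 replicates 1 and 3.

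Exons and junctions of some genes changed severalfold relative to the rest of their gene. Among probe sets that fell relative to their gene with all 3 hairpins, the junction JUC10000400.hg.1 of ATP5F1C, the gamma subunit of ATP synthase (ATP5C1 on the array), was 11.6-fold, 5.38-fold and 11.5-fold lower with shRNA1, shRNA2 and shRNA3 (log2 -3.54, -2.43 and -3.53; SE 0.22). A junction of HYCC1 (JUC07009127.hg.1) changed by -3.45, -2.05 and -4.68 (SE 0.12), and 1 of CLSTN1 (JUC01018045.hg.1), a calsyntenin, by -3.46, -1.74 and -3.51 (SE 0.18). Others that fell lay in PICALM, a clathrin assembly gene (-2.88, -1.69 and -2.30; SE 0.13), NFYA, a subunit of a CCAAT-binding factor (-2.27, -1.61 and -1.95; SE 0.12), SPAG9, a kinase scaffold (-2.56, -1.54 and -2.47; SE 0.18), MPRIP (-2.31, -1.32 and -2.33; SE 0.11), EPB41L2 (-3.49, -1.23 and -3.16; SE 0.11) and CLASP2, which binds microtubule ends (-1.76, -1.23 and -1.80; SE 0.13). The junction of the cytoskeletal linker DST changed by -2.19, -1.46 and -2.41, and lost its call without control replicate 3 (largest adjusted p = 0.0576). With shRNA1 and shRNA3 the signals of the junctions of ATP5F1C (5.95 and 5.86), HYCC1 (6.49 and 5.09), CLSTN1 (6.42 and 6.46), SPAG9 (5.99 and 6.07), DST (6.03 and 5.75) and CLASP2 (6.43 and 6.40) lay below the level cutoff of 6.53, so these falls may be larger than measured.

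The junction whose smallest rise among the 3 hairpins was largest was JUC01003154.hg.1 of EPB41, the erythrocyte membrane protein gene, at 5.48-fold, 2.99-fold and 4.61-fold (log2 2.45, 1.58 and 2.20; SE 0.08). Junctions of the cytoskeletal gene SEPTIN6 (5.11-fold, 2.82-fold and 4.68-fold; SE 0.11 on the log2 scale), GOLIM4, a Golgi protein (2.15, 1.40 and 2.15; SE 0.10), HYCC1 (JUC07009142.hg.1; 1.73, 1.54 and 1.58; SE 0.16), the Golgi matrix gene GOLGA2 (1.55, 1.24 and 1.27; SE 0.12) and APBB2 (1.57, 1.00 and 1.37; SE 0.11) also rose. HYCC1 thus held junctions that changed in opposite directions. The control signal of the junctions of SEPTIN6 (6.09), DIAPH2 (6.24) and PSMA1 (6.35) lay below the cutoff, so that these rises may be understated. A junction of ESYT2 (1.35, 1.02 and 1.16) lost its call in all 3 without control replicate 3 (largest adjusted p = 0.0566). A junction of the formin DIAPH2 (2.20, 1.11 and 1.83) lost it without control replicates 2 or 3 (largest adjusted p = 0.0976 and 0.134), shRNA1 replicates 2 or 3 (0.0562 and 0.0585) or shRNA2 replicates 1, 2 or 3 (0.0799, 0.0662 and 0.0872). NDUFA12 of respiratory complex I (1.27, 1.34 and 1.61) lost it without control replicates 1, 2 or 3 (0.107, 0.0543 and 0.110), shRNA1 replicates 1, 2 or 3 (0.0883, 0.135 and 0.0851) or shRNA2 replicate 3 (0.0578). The proteasome gene PSMA1 (1.09, 1.18 and 1.19) lost it without control replicates 1 or 2 (0.119 and 0.108), shRNA1 replicates 1, 2 or 3 (0.117, 0.117 and 0.135), shRNA2 replicates 2 or 3 (0.0520 and 0.0646) or shRNA3 replicates 1 or 2 (0.0885 and 0.0589).

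**Figure D3:**
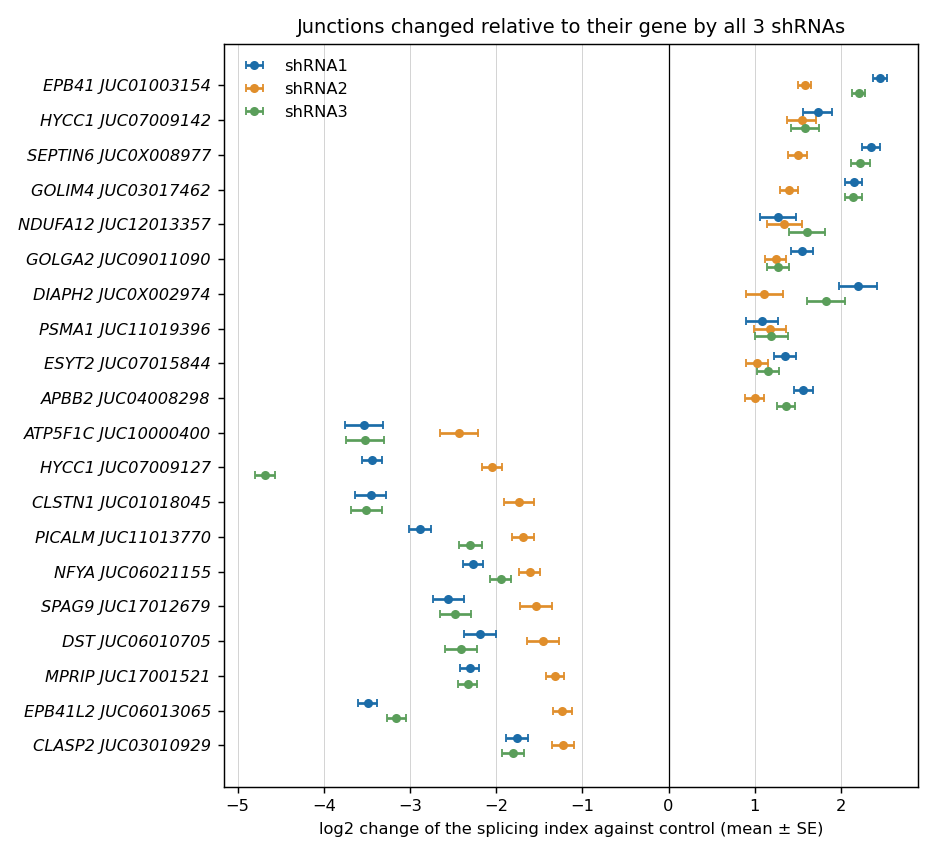
Log2 change of the splicing index against control (horizontal axis; points are fitted means, bars are ± SE) for the 10 highest and 10 lowest probe sets, all of them junctions, called with all 3 hairpins. Changes with shRNA2 lay nearer to 0 than those with shRNA1 and shRNA3 for most junctions, as for EPB41L2 (-1.23 against -3.49 and -3.16).

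In all, 161 probe sets in 107 genes changed relative to their gene with all 3 hairpins, 59 higher and 102 lower. They were 72 junctions and 30 exons that fell and 48 junctions and 11 exons that rose, and 12 genes held both directions. AP1S2, chosen after its values were seen, held the most, with 4 lower and 3 higher. Of the 107 genes, 21 also changed at the gene level with all 3 hairpins and 37 were not called at the gene level with any. Median changes of the lower probe sets were -1.38, -0.83 and -1.26 with shRNA1, shRNA2 and shRNA3, and those of the higher ones 1.02, 0.83 and 0.92. The count of 161 was 68 without control replicate 3, 107 without shRNA1 replicate 2 and 101 without shRNA2 replicate 3.

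Against control alone, 540 probe sets changed with shRNA1 (262 higher, 278 lower), 920 with shRNA2 (578 higher, 342 lower) and 815 with shRNA3 (329 higher, 486 lower). Between hairpins 74 differed for shRNA2 minus shRNA1, 13 for shRNA3 minus shRNA1 and 79 for shRNA3 minus shRNA2. The shRNA1 count was 338 and 324 without control replicates 1 and 3 and 289 and 308 without shRNA1 replicates 2 and 3. The shRNA2 count was 557, 496 and 146 without control replicates 1, 2 and 3 and 332 without shRNA2 replicate 3, and fell to 58 when only the control and shRNA2 arrays were fitted and to 535 with the replicate number as a block. The shRNA3 count was 458 and 353 without control replicates 1 and 3 and 312 without shRNA3 replicate 1.

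Known RBFOX splicing targets were enriched among these genes. Of 48 listed targets that could be tested, 14 held a probe set changed with all 3 hairpins (29.2%): ENAH, FN1, PICALM, EPB41, CLSTN1, NDEL1, LRRFIP2, NUMA1, GOLIM4, TPM1, KIF1B, DST, ADD3 and TJP1. In a permutation test, random lists of the same size held 0.638 on average and at most 6 (10000 lists, one-sided p = 1e-04, the smallest this number of lists can give). Junction JUC01031071.hg.1 of ENAH, an actin regulator, changed by -2.39, -0.86 and -2.36 (SE 0.10), exon probe set PSR02044166.hg.1 of fibronectin (FN1) by -2.61, -0.86 and -2.28 (SE 0.08), and junction JUC17001153.hg.1 of NDEL1, a dynein regulator, by -2.25, -0.98 and -1.63 (SE 0.07). These probe sets were chosen after their values were seen. With single hairpins 28, 18 and 20 targets held a called probe set. With shRNA1 and shRNA3 these include RBFOX2 itself, which is on the list. With the mean of the 3 hairpins 23 did (47.9%; random lists held 3.09 on average and at most 12, permutation p = 1e-04). Among the 23 were RBFOX2, the silenced gene, and its paralog RBFOX1. Without control replicate 3 the 14 targets became 7.

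The list of the integrated stress response, which the factor ATF4 controls, was called higher with each hairpin by camera at the preset correlation. Of 23 measured members, 17 rose with shRNA1, 19 with shRNA2 and 9 with shRNA3, and none fell (19, 20 and 12 higher when adjusted over the list alone). Medians were 0.23, 0.24 and 0.10, with camera adjusted p = 5.59e-19, 2.31e-16 and 0.00215, but adjusted p = 0.155, 0.155 and 0.524 with an estimated correlation. The asparagine synthetase gene ASNS rose by 0.49, 0.49 and 0.30, and 9 members including DDIT4 rose with all 3 hairpins. DDIT3 changed by 0.73, 0.60 and 0.28, but was not called with all 3 without control replicate 1 (largest adjusted p = 0.0602) or shRNA3 replicate 1 (0.0764). The list of hypoxia and glycolysis was called in the same direction. Of 21 measured, 15, 12 and 18 rose and none fell (16, 16 and 19 adjusted over the list alone), with medians of 0.27, 0.19 and 0.29. Their camera adjusted p was 7.16e-14, 1.76e-09 and 3.71e-10, against adjusted p = 0.442, 0.552 and 0.524 with an estimated correlation. SLC2A3, the kinase PDK1 (0.56, 0.50 and 0.63), NDRG1 (0.44, 0.42 and 0.57) and the collagen hydroxylase P4HA1 (0.50, 0.39 and 0.48) were among the 11 members that rose with all 3.

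Oxidative phosphorylation was the other list called with each hairpin. Of 22 measured genes 3, 3 and 6 fell and none rose (5, 4 and 7 lower adjusted over the list alone), with medians of -0.05, -0.06 and -0.07. Its camera adjusted p was 0.0435, 0.0135 and 0.0135, against adjusted p = 0.748, 0.649 and 0.649 with an estimated correlation. The gene value of ATP5F1C changed by -0.15 ± 0.03 as a mean over the 3 hairpins. It includes the junction described above, which changed by a mean of -3.16 relative to the gene's other probe sets. A fall of the whole gene is thus not shown. Camera called 29 of the 120 list tests at the preset correlation and 0 with an estimated correlation, where 45 and 13 had an unadjusted p below 0.05, and fry called 42. Other splits of the 12 arrays gave as many called lists in 37 of 100 draws, the real one included.

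**Figure D4:**
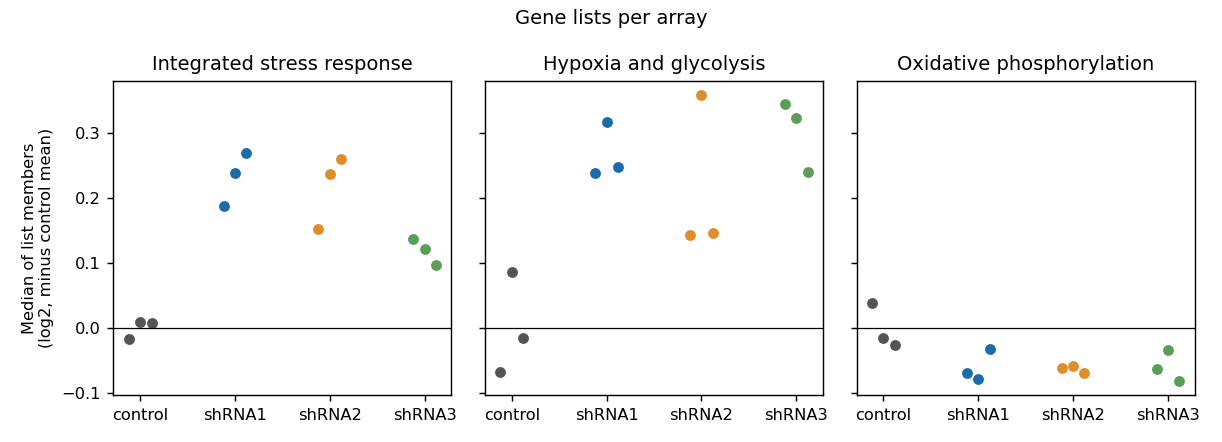
Median over list members of the log2 value minus the control mean, for each of the 12 arrays by group, for the integrated stress response, hypoxia and glycolysis, and oxidative phosphorylation. Each point is 1 array, and the first 2 lists lay above the control arrays and the last lay lower with every hairpin.

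Several lists were called with single hairpins. With shRNA2, 11 of 20 p53 targets fell and 2 rose (14 lower and 2 higher adjusted over the list alone; camera adjusted p = 3.34e-06, and adjusted p = 0.426 with an estimated correlation). The p53 targets ZMAT3 and RRM2B changed by -0.25 ± 0.04 and -0.19 ± 0.03 as means over the 3 hairpins. Of this list, GADD45A was called higher and BAX, FAS and AEN lower with all 3 hairpins. The calls of GADD45A and BAX were lost without single arrays. With shRNA3, 8 of 19 genes of G2 and mitosis fell (9 adjusted over the list alone; adjusted p = 0.00198, and adjusted p = 0.649 with an estimated correlation), as did 10 of 23 of DNA replication (10 adjusted over the list alone; 0.00535, and adjusted p = 0.552 with an estimated correlation), including CCNE2 with a mean change of -0.26 ± 0.05, while MCM7 rose with each hairpin (0.27, 0.25 and 0.24). Also with shRNA3, 4 of 11 nonsense-mediated decay factors fell (4 adjusted over the list alone; 0.00888, and adjusted p = 0.491 with an estimated correlation), among them SMG8 (mean -0.28 ± 0.06). Of 11 genes of the RNA interference machinery, 4 fell and 1 rose with shRNA3 (5 and 1 adjusted over the list alone; 0.0205, and adjusted p = 0.552 with an estimated correlation), AGO1 among the falls (mean -0.19 ± 0.03). The 1 that rose, AGO4, was called higher with all 3 hairpins. That call was lost without control replicates 1 or 3 or shRNA2 replicates 2 or 3. Of 32 splicing regulators, 10 fell and 2 rose with shRNA3 (11 and 4 adjusted over the list alone; 0.0248, and adjusted p = 0.552 with an estimated correlation), with a mean change of CELF1 of -0.16 ± 0.03.

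The list of cholesterol synthesis was called lower with shRNA1 (3 of 17 fell, 8 adjusted over the list alone; camera adjusted p = 0.00888, and adjusted p = 0.442 with an estimated correlation) and with shRNA3 (7 fell and 1 rose, 9 and 2 adjusted over the list alone; 0.0135, and adjusted p = 0.442 with an estimated correlation). HMGCS1, which makes HMG-CoA, had a mean change of -0.21 ± 0.03. Immediate early genes were called higher with shRNA1 (3 of 19 rose, 3 adjusted over the list alone; 0.0435, and adjusted p = 0.77 with an estimated correlation) and with shRNA3 (7 rose and 1 fell, 8 and 1 adjusted over the list alone; 0.0135, and adjusted p = 0.701 with an estimated correlation). MYC had a mean change of 0.16 ± 0.04. With shRNA1, 5 of 16 endoplasmic reticulum chaperone and unfolded protein genes rose and 1 fell (6 and 2 adjusted over the list alone; 0.0127, and adjusted p = 0.552 with an estimated correlation), HERPUD1 and XBP1 among the rises (means of 0.25 ± 0.03 and 0.21 ± 0.04). The same list was not called with the other hairpins, where 3 rose and 4 fell with shRNA2 (median -0.04; adjusted p = 0.681) and none rose and 5 fell with shRNA3 (median -0.07; adjusted p = 0.0782). Epithelial markers were called higher with shRNA3 (5 of 12 rose and 1 fell, 7 and 1 adjusted over the list alone; 0.0435, and adjusted p = 0.442 with an estimated correlation), with a mean change of CDH1, E-cadherin, of 0.24 ± 0.04. Of 6 drug transport genes 2 fell with shRNA1 (2 adjusted over the list alone; 0.0435, and adjusted p = 0.442 with an estimated correlation). They were the efflux pumps ABCB1 (-0.31, -0.23 and -0.26 with the 3 hairpins) and ABCG2 (-0.18, -0.16 and -0.13), and the mean change of ABCG2 was 0.0036 (adjusted p = 0.962) when probe sets were kept above the 60th percentile. The list of the 3 RBFOX genes was called lower with shRNA1 through RBFOX2 alone (adjusted p = 0.0135, and adjusted p = 0.426 with an estimated correlation).

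Of 4 measured histone genes, a number too small for a list test, H2BC5, H2BC11 (-0.41, -0.44 and -0.22) and H2BC12 (-0.30, -0.30 and -0.32) fell with all 3 hairpins and H1-4 was not called. The 3 measured snoRNA host genes were not tested as a list, and no mitochondrially encoded gene was measured. Camera at the preset correlation made no call in any contrast for the lists of 48 RBFOX targets at the gene level, 10 SR proteins, 16 hnRNPs, 14 mesenchymal markers, 21 interferon response genes, 26 TGF-beta and matrix genes, 20 Notch and Wnt genes, 22 actin genes, 16 neuronal markers, 12 kidney and adrenal lineage genes, 29 large and 21 small ribosomal subunit genes. Of these, fry called RBFOX targets, SR proteins and hnRNPs lower with shRNA3 (adjusted p = 0.0153, 0.00566 and 0.00384) and hnRNPs lower in the mean of the 3 hairpins (adjusted p = 0.0342). The RBFOX targets include RBFOX2, the silenced gene, which changed by -0.74 with shRNA3, and fry was not repeated without it. A fall of the other targets as a set is thus not shown. Markers of other cell types were not called either, namely 12 of hepatocytes, 9 of erythroid cells and 10 of fibroblasts. Within these lists, the neuronal enolase ENO2 rose with all 3 hairpins (0.48, 0.34 and 0.40), as did STAT2 (0.25, 0.22 and 0.23) and KIF1B (0.30, 0.28 and 0.34). LGR5, of the Notch and Wnt list, fell with all 3 hairpins (-0.23, -0.26 and -0.33). Median and mean differed in sign in tests that were not called, as for RBFOX targets with the mean of the 3 hairpins (0.00 and -0.01) and for Notch and Wnt genes with shRNA3 (0.01 and -0.02), and in no called test.

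Changes of the hairpins were correlated across genes, which are not independent replicates. Observed r was 0.763 for shRNA1 and shRNA2, 0.651 for shRNA1 and shRNA3 and 0.747 for shRNA2 and shRNA3. Simulated unchanged groups with a shared simulated control group, each gene drawn independently, gave 0.498, 0.499 and 0.5. Over all genes the share with the same sign was 74.3%, 65.1% and 76.7% against 66.6%, 66.8% and 66.7% without effect. For shRNA1 and shRNA3 it was thus no higher than in the simulation. The median change over all genes was -0.0135 with shRNA1 and 0.0185 with shRNA3, and such opposite shifts can lower the share. Covariances were 0.00781, 0.00798 and 0.00985 against simulated values of 0.00129, 0.00129 and 0.0013, an excess of 0.00651, 0.00669 and 0.00855. Genes higher with both hairpins numbered 550, 653 and 638, where independent lists would give 59.1, 120 and 118, and genes lower with both numbered 447, 472 and 980, where independent lists would give 58.4, 100 and 213. For genes called with all 3 hairpins, 20 simulations without effect gave at most 0, and independent lists would give 7.10 higher and 8.66 lower. For the splicing index r was 0.740, 0.595 and 0.590 against 0.501, 0.5 and 0.501 without effect, with 76.5%, 69.1% and 69.4% of the same sign against 66.7% in each pair without effect and an excess covariance of 0.0118, 0.00772 and 0.00924. No hairpin was set against control arrays of its own, and the simulation drew genes independently, so part of the excess may come from the shared controls.

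Single probe sets, including those without a gene name, gave 8737 calls with shRNA1 (6374 higher, 2363 lower), 22494 with shRNA2 (11717 higher, 10777 lower) and 30369 with shRNA3 (13321 higher, 17048 lower) among 516081 tested, and 3414 with all 3 (2386 higher, 1028 lower). These counts moved by more than 1.5 times with many arrays. The shRNA1 count was 2195, 4368 and 2508 without control replicates 1, 2 and 3, 2834, 1548 and 2874 without shRNA1 replicates 1, 2 and 3, and 13333 without shRNA2 replicate 1. The shRNA2 count was 6207, 11140 and 3346 without the control replicates in that order, 8754 and 8307 without shRNA2 replicates 2 and 3, and 14237 with the replicate number as a block. The shRNA3 count was 8618, 17818 and 8927 without the control replicates, and 5889, 18026 and 15583 without shRNA3 replicates 1, 2 and 3. The count for all 3 was 849, 1950 and 741 without the control replicates, 1493, 936 and 1528 without those of shRNA1, 5899, 1892 and 1886 without those of shRNA2, and 1423 and 2049 without shRNA3 replicates 1 and 2.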

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

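The tests that weigh the 3 patterns below, and the split test for lists called with each hairpin, were chosen only after the results were seen, and the other tests on splits of the arrays were set beforehand. The slopes over common probe sets and genes took the place of slopes over all those called with shRNA3 (-0.27 over 808 probe sets and 0.07 over 4467 genes). When leaving out each array, these ranged from -0.301 to -0.233 and from -0.0703 to 0.193.

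The first pattern is that exons and junctions changed less relative to their gene with shRNA2, which lowered RBFOX2 least, than with shRNA1. Compression of a probe set while its whole gene changes needs a gene change at least as large as the index change. It was argued against for the 161 common probe sets, since the median index change was 1.05 and that of their genes 0.11. The index change was larger in 100% of them (exact interval 97.7% to 100%). They were chosen by their index change, so this share is no separate test. A size in proportion to the loss of RBFOX2 stays open, since slopes of a hairpin difference against the change with the other hairpin were split. These share no array. For shRNA2 minus shRNA1 the slope was -0.402 (-0.409 to -0.391 when leaving out each array, RBFOX2: -0.776). For shRNA3 minus shRNA2 it was 0.332 (0.321 to 0.345, RBFOX2: 0.273), and both lay nearer to RBFOX2 than to 0. For shRNA3 minus shRNA1 it was -0.0735 (-0.0971 to -0.0439, RBFOX2: -0.638), nearer to 0. The first of these slopes restates the pattern and lay nearer to 0 over the 808 probe sets called with shRNA3 (-0.27), and over the 133 common probe sets above the level cutoff in every group they were -0.409, 0.317 and -0.0926. Counts of calls gave no stable order, with most for shRNA2 (920) at 1.5-fold and fewest at 2-fold (160, 87 and 139), and any other property in which the hairpins differ stays open as well.

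The second pattern is that levels of whole genes changed with all 3 hairpins, whatever the loss of RBFOX2. Over the 778 common genes other than RBFOX2 the slope of shRNA3 minus shRNA1 was 0.0483 (-0.00138 to 0.111 when leaving out each array, RBFOX2: -0.638). That of shRNA2 minus shRNA1 was -0.0159 (-0.141 to 0.123, RBFOX2: -0.776), and that of shRNA3 minus shRNA2 (0.065, -0.0784 to 0.192, RBFOX2: 0.273) did not decide. Choosing genes called with all 3 hairpins can draw such slopes towards 0. Over the 2421 genes called with shRNA2, whatever the other hairpins gave, the slope of shRNA3 minus shRNA1 was 0.1 (0.0444 to 0.155). Its sign was opposite to that of RBFOX2, which argues against a size in proportion to the loss of RBFOX2 RNA for these genes as a set. The other slopes over genes called with a single hairpin (0.0702 and 0.042) had no stable sign. Within the stress and hypoxia lists, the slope of shRNA3 minus shRNA1 had the sign of RBFOX2. It was -0.302 (19 genes, -0.428 to -0.192) and -0.253 (12 genes, -0.339 to -0.145), while their other slopes had no stable sign. A size in proportion thus stays open for these lists. Chance values of the shared control arrays stay open as a cause of the common calls. The highest count of common genes in simulated unchanged groups was 0 against 779. However, the simulation drew each gene independently, while the real arrays may deviate in many genes together, so it cannot decide. The count also fell to 242 without control replicate 1. Over all genes the share with the same sign for shRNA1 and shRNA3 (65.1%) was no higher than without effect (66.8%). Opposite median changes of these hairpins can lower that share. A difference of the control cultures or of the control hairpin, unrelated to RBFOX2, may give such a pattern and cannot be told apart from a response to RBFOX2 that is not in proportion, since there was 1 control hairpin.

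The last pattern is that some genes changed with 1 hairpin alone, or more than with the others, being called in the same direction against control and against both other hairpins. Of 325 such genes, 295 changed most with shRNA2 or shRNA3, such as NKIRAS2 and TAF13 or NEK7 and CERS5. Their measured size did not follow the loss of RBFOX2, since shRNA1 lowered it most, but this follows from how they were chosen. It is thus no separate test. How many of them are false calls is not known, because the rate of a single contrast does not carry over to genes called in several. The count of 325 was not repeated without single arrays. For the 30 genes of shRNA1, such as CEMIP2, an effect of RBFOX2 loss and an effect of the hairpin cannot be told apart, because that hairpin also gave the largest loss. Falls made up 76% of the 325 (247 lower and 78 higher; exact interval 71.0% to 80.5%), against 54.7% expected from the share of falls among all calls of each hairpin, with 56.7% against 40.4% for shRNA1, 81.2% against 59.3% for shRNA2 and 77.1% against 55.3% for shRNA3. The excess is consistent with silencing of other transcripts by a hairpin, but genes are not independent, the interval for shRNA1 alone (37.4% to 74.5%) holds its expected share, and hairpin sequences and seed matches were not used here.

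Other splits of the arrays were compared with the real groups. For the mean of the 3 hairpins, the real 3853 genes were reached in 1 of 100 splits, the real one, and the highest other gave 1626. The 779 genes common to all 3 were reached in 1 of 100 splits as well, with 0 as the highest other. Of 40 splits, 1 each reached the 161 common probe sets relative to gene, the 14 known targets and the 3414 common single probe sets. The highest other gave 0 each. A random assignment of these arrays to groups was thus argued against for these counts. Chance differences between cultures stay open, since nothing says that replicates were separate cultures. Chance could not be excluded for the gene lists, where 37 of 100 splits gave at least the 29 calls and the highest other gave 58, nor for the 3 lists called in one direction with each hairpin, which 20 of 100 splits reached, with up to 8. Comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. The highest other split gave 0 genes against 1675, 2422 and 4468 for the single hairpins, 1, 0 and 1 against 198, 1182 and 593 between hairpins, 1, 0 and 0 against 540, 920 and 815 probe sets relative to gene, and 0 each against 8737, 22494 and 30369 single probe sets.

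The level of RBFOX2 differed between hairpins, by 0.58 for shRNA2 minus shRNA1, 0.29 for shRNA3 minus shRNA1 and -0.28 for shRNA3 minus shRNA2. In opposite directions with shRNA1 and shRNA2, and different between them by test, were 3 genes, ADD3 (-0.19 and 0.17), NMNAT2 (0.16 and -0.17) and CA2 (-0.13 and 0.15), chosen after their values were seen. For shRNA1 and shRNA3 there were 15 such genes, with the largest difference in CLGN (0.29 and -0.42). For shRNA2 and shRNA3 there were also 15, with the largest in SELENOP (-0.32 and 0.31). Outside the gene comparisons, 344 probe sets with no gene name changed with all 3 hairpins, 240 higher and 104 lower, which is 0.462% of the 74434 unnamed probe sets tested, against 0.695% of the others. A further 104 probe sets with several gene names changed with all 3 hairpins.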

How the results depend on the processing

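The count with identical copies kept and the shortened gene lists were chosen only after the results were seen. Of the values that answer a comparison, 309 kept their direction and side of the threshold, or a count within 1.5 times, 146 counts moved by more and 1 value fell short of a threshold. Quantile normalization and centring of arrays moved no count by more than 1.5 times, and 765 and 709 of the 779 common genes stayed common under them. Fewer stayed common without a level filter (380), with only the compared groups (443) and with the median of probe sets (217). Of the 161 common probe sets, 67 stayed without a filter, 41 with only the compared groups and 80 with array weights. The cause of the moves was not tested where nothing else is said. Without a level filter, 114 genes differed between shRNA2 and shRNA1, 453 were common to all 3, and counts relative to gene were 198 for shRNA2, 477 for shRNA3 and 85 for all 3, with 9 known targets. Single probe sets were then 2073, 3138 and 7750, and 584 for all 3. With the 60th percentile they were 351, 582 and 439 relative to gene and 106 for all 3, and 5245 single probe sets were common. With the median of probe sets as the gene value, counts were 643, 1369 and 2239 for single hairpins, 2178 for their mean, 79, 292 and 232 between hairpins and 294 for all 3. With a trended robust prior, single probe sets were 17095 for shRNA1, 35908 for shRNA2 and 6452 for all 3. Array weights gave 3761 genes for shRNA1, 5406 for shRNA3 minus shRNA1 and 308 for shRNA3 minus shRNA2, 1349, 164 and 1331 probe sets relative to gene and 86 for all 3, and 43860, 4782 and 58650 single probe sets. With only the compared groups in the fit (fewer arrays for the spread), genes were 973 for shRNA2 and 89, 3347 and 170 between hairpins. Probe sets relative to gene were then 58 for shRNA2, 457 for shRNA3 and 41 for all 3, known targets 9, and single probe sets 1784 for shRNA2 and 600 for all 3. By construction, a 1.5-fold threshold left 18, 16 and 22 genes, 14 for the mean, 2, 3 and 6 between hairpins and 9 for all 3, and RBFOX2 with shRNA2 (-0.46) fell short of it. With no minimum size 1375, 4660 and 3335 probe sets changed relative to gene, 453 with all 3, and 22 known targets. With 2-fold as the minimum there were 160, 87 and 139, 34 with all 3, and 5 known targets. Called in the mean of the hairpins, known targets were 23. With an estimated correlation, 0 gene lists were called and 13 tests had an unadjusted p below 0.05. The motif search and its shorter window were not run.

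Replicate numbers did not pair the arrays of most groups. Same-numbered arrays deviated together (r above 0.1) in 5 of 18 pairs over genes and 1 of 18 over the splicing index, and 5 and 2 matched best with their own number. Over genes, all 3 pairs of control and shRNA2 arrays deviated together (0.202, 0.432 and 0.264), each best with its own number, but not over the splicing index (0.0253, 0.0252 and 0.0784). With the replicate number as a block, 2341 genes were called with shRNA2, 535 probe sets changed relative to gene and 14237 single probe sets changed with shRNA2, and other counts stayed within 1.5 times. Leaving out each array, RBFOX2 ranged from -1.06 to -1.02, -0.48 to -0.45 and -0.75 to -0.74. Genes ranged from 493 to 2201, 1071 to 3323 and 2186 to 5184 for the single hairpins, 1867 to 4649 for their mean, 242 to 1233 for all 3, and 83 to 200, 291 to 2508 and 245 to 1485 between hairpins. Probe sets relative to gene ranged from 289 to 627, 146 to 1076 and 312 to 923, and 68 to 188 for all 3, with 7 to 15 known targets. Single probe sets ranged from 1548 to 13333, 3346 to 26030 and 5889 to 38730, and 741 to 5899 for all 3. Among single named genes and probe sets 4571 values stayed on their side, 236 fell short, 52 newly passed, 31 uncalled values moved and 2 reversed. The reversed ones were ABCG2 in the mean of the hairpins with the 60th percentile (0.0036) and IER2 with the median of probe sets (-0.0046). Of 50 genes and 50 probe sets named as changed by all 3, 19 and 23 lost that call without at least 1 array. Without shared and named members the stress and hypoxia lists kept 14, 16 and 7 and 14, 11 and 17 higher genes of 20 each. Signal near the level filter limits what dim probe sets can show.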

Other observations

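The slopes below were chosen only after the results were seen. Single genes of lists that were not called also changed in the mean of the hairpins. Neurofilament NEFM was higher by 0.42 ± 0.07 as a mean over the 3 hairpins, with fitted differences of 0.25, 0.37 and 0.66 for shRNA1, shRNA2 and shRNA3, while the intermediate filament INA changed by a mean of -0.28 ± 0.05 (-0.11, -0.26 and -0.49). In the TGF-beta and matrix list, ID1 had a mean change of -0.25 ± 0.05 beside the fall of ID3, and the mesenchymal marker SPARC a mean change of 0.22 ± 0.04.

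Slopes of the difference between hairpins were set apart by gene, and no test compared them. For probe sets of known RBFOX targets the slope of shRNA2 minus shRNA1 against shRNA3 was -0.48 (55 probe sets; -0.49 to -0.47 when leaving out each array), and for other genes -0.21 (753 probe sets; -0.25 to -0.17), where RBFOX2 gave -0.78. The slopes of shRNA3 minus shRNA2 against shRNA1 were 0.38 (63, 0.365 to 0.393) and 0.22 (469, 0.202 to 0.239), where RBFOX2 gave 0.27. Those of shRNA3 minus shRNA1 against shRNA2 were -0.14 (46, -0.18 to -0.108) and -0.09 (874, -0.136 to -0.0504), where it gave -0.64. Of these pairs of values, known targets lay nearer to RBFOX2 in the first and last and other genes in the middle one. In the last pair the ranges overlapped, so it gives no stable order. At the gene level, over the called genes, slopes of the stress list were -0.08, -0.30 and -0.09 against shRNA3, shRNA2 and shRNA1. Leaving out each array, they ranged from -0.238 to 0.0962, -0.428 to -0.192 and -0.26 to 0.0995. Those of the hypoxia list were -0.15, -0.25 and 0.01, with ranges of -0.255 to 0.0139, -0.339 to -0.145 and -0.147 to 0.115. The median of the hypoxia list was higher with shRNA3 (0.29) than with shRNA1 (0.27).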
